A study of Mus musculus with 2 samples.

How the data were processed

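The samples were 1 library of normal colon tissue (IEL) and 1 of colon tumor (TIL), both labelled as γδ T lymphocytes of C57BL/6J mice aged 18 to 20 weeks. Per the labels, tissue was minced and digested, and cells were taken from the 40%/70% interface of a Percoll gradient; the protocol text names tumour tissue for both samples and gives no sort or gate. Libraries were 10x Genomics single-cell 3' v3. The submitters' processing notes name Cell Ranger 6.1.1 and the mm10 build, and the matrix headers name the same Cell Ranger version. The deposited matrices hold whole-number UMI counts per gene and cell barcode, per the file headers, with no normalization by the authors. How barcodes were called as cells is not stated, and the lowest barcode totals were 500 (IEL) and 501 (TIL) UMIs.

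Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs, which kept 97.1% of IEL and 93.7% of TIL barcodes. Both libraries were clustered together without batch correction, since library and tissue are confounded. Counts per 10000 were log-transformed, and 2000 variable genes, 30 principal components and a graph of 15 neighbours were used for Leiden clustering at resolution 1.0 (igraph 0.11.9), which gave 21 clusters. T cell receptor segments, inhibitory receptors, exhaustion-associated regulators, mitochondrial, immunoglobulin, haemoglobin and sex-linked genes were kept out of the variable genes. Scrublet (through Scanpy 1.11.5) called 0 doublets in either library at its automatic threshold, which was taken as not working, so no doublets were removed on its calls. Its scores served only to leave a cluster with a median score above 0.2 unnamed as mixed; that cluster, number 13, also had a median of 12279 UMIs.

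A cluster was named for another cell type when at least 3 of that type's fixed markers reached 50 CPM and 4-fold over the other cells, and otherwise as γδ T-like when at least 3 fixed γδ T markers reached 50 CPM. It was left unnamed where its median UMIs were far below its library's, or where markers of another type outnumbered its own among its 10 leading genes. The cluster that this rule named macrophage or monocyte-like is called myeloid-like here, since 4 of its 10 leading genes are fixed neutrophil markers. A subset was the one with the largest share of its fixed markers at 50 CPM or more. Markers and gene lists were fixed before the data were examined. Naming subsets by the share of markers detected, the limit on the median doublet score, and setting apart droplets with at least 5% haemoglobin UMIs were chosen after the data were seen. Genes that define a subset are not reported as results of contrasts between subsets of 1 library; only genes kept out of the clustering are.

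Expression was summed over the cells of a class or subset in each library and given as CPM. Ratios have exact 95% intervals conditional on the summed counts of both libraries, and shares have exact Clopper-Pearson 95% intervals; both treat UMIs or cells as independent and cover counting error only. A gene was counted as apart when it had at least 20 CPM in either library, a ratio of at least 2-fold and an interval excluding 1. A count of 0 was set to a floor of 3 UMIs over the library, and the ratio is then a bound. No p-value was computed, since each group had 1 library. The named genes were the 15 furthest apart in each direction, without ribosomal, mitochondrial, haemoglobin, immunoglobulin, sex-linked, receptor segment and unnamed model genes. To these were added the members of each fixed list with the largest ratios, and Pdcd1, Havcr2, Lag3, Tigit, Ctla4, Il17a, Ifng, Gzmb, Tox, Tcf7 and Trdc. Further list members, such as those against the direction of their list or well-known markers such as Nkg7, were picked after their values were seen. For contrasts of subsets, the 10 furthest in each direction were ranked by the same rule and some of them are named. Gene positions are GRCm38 coordinates.

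Each fixed list's median log2 ratio was placed among medians of 10000 random lists matched on size and expression. The lists were inhibitory receptors, exhaustion-associated regulators, cytotoxic and type-1, intraepithelial residence, naive and memory-like, co-stimulation, tissue repair, chemokine receptors and homing, cell cycle, glycolysis and hypoxia, oxidative phosphorylation, lipid handling, type I interferon, dissociation stress, apoptosis and RNA quality, γδ receptor genes, antigen presentation and sex-linked genes. Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs without replacement. Over 20 draws, the share of TIL γδ T-like cells with at least 2 inhibitory receptors lay between 49.9% and 51.1%, and that of IEL cells between 6.26% and 7.49%. It lay between 8.12% and 11.6% in TIL and between 6.17% and 7.40% in IEL cytotoxic-like cells. Free RNA in TIL cytotoxic-like cells was estimated by a method chosen after the data were seen. It was given the make-up of all TIL cells passing the filter and a scale of 2.28%, at which it accounts for all Il17a UMIs of these cells. Ratios without it were taken by subtracting its part from the TIL level. For the share with at least 2 receptors, each receptor UMI was dropped with the free RNA part of its gene's level, and the median of 20 draws (7.04% to 10.6%) is given.

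The ratios were tested on simulated data made from these depths. All genes with simulated 3-fold and 5-fold differences were called, 58.0% of those with 2-fold, and 0 of 5543 unmoved genes. The simulated counts varied by counting error alone around a shared profile. They therefore give no rate of false calls from differences between animals, library preparations or handling. Of simulated lists moved by 1 on the log2 scale, 97.0% lay outside the middle 95% of random lists, against 8.0% of unmoved lists. Alternatives varied the filters on cells, removal of high-UMI cells, clustering resolution, centring by library, a cell-wise rule, scaling, cell weights, expression floor, fold, depth and number of receptors. Keeping haemoglobin-rich droplets, and clustering with receptor genes, were added after the data were seen. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. Another subset of γδ T-like cells, with the gene list and contrasts that rest on it, is not reported here. Variable-segment sequences and clonotypes were not analysed here, as the deposited files hold gene counts alone.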

Results

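The study profiled γδ T cells of C57BL/6J mice by droplet single-cell RNA sequencing of transcript 3' ends, with 1 library from normal colon tissue (labelled IEL) and 1 from colon tumor (labelled TIL). The IEL library held 9398 cell barcodes with 69414155 unique molecular identifiers (UMIs), and the TIL library 13245 barcodes with 94953893 UMIs. After filtering, 9128 IEL cells (median 6858.5 UMIs and 2421 genes) and 12407 TIL cells (median 6465 UMIs and 2219 genes) remained. With 1 library per group there was no replicate check, so every difference is between these 2 libraries, and the 95% intervals in brackets cover counting error only. Ratios are of UMIs of a gene per 1000000 UMIs (CPM), TIL over IEL unless stated.

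The first question was which cells each library held. Nearly all droplets lay in clusters named γδ T-like: 99.4% of IEL cells (99.2 to 99.5) and 94.5% of TIL cells (94.1 to 94.9). That name needed 3 of the fixed γδ T markers at 50 CPM, which include Cd3e, Cd3g and Cd3d, shared by all T cells. The myeloid-like and epithelial-like clusters had 6 and 5 of these markers, so the shares do not measure γδ purity. The TIL library also held 1.80% myeloid-like cells, led by S100a9, S100a8, Apoe, Il1b and Lyz2 transcripts, against 0.0110% of the IEL library. Markers of macrophages or monocytes and of neutrophils lay in this 1 cluster, from which 56 neutrophil-like cells split off at Leiden resolution 2.0, and 31 under a stricter filter on cells. Epithelial-like cells, led by immunoglobulin transcripts and Krt8, made up 0.403% of TIL and 0.110% of IEL cells, but 0.167% and 0.925% under a looser filter on cells, and no cluster was named so under a stricter one. Droplets of a cluster that mixed markers of several γδ T subsets and carried high doublet scores were left unnamed, 2.94% of TIL and 0.197% of IEL cells, or 2.45% and 1.83% with genes centred within each library. A further 0.177% of TIL and 0.329% of IEL cells were unnamed for low UMI totals. At least 5% haemoglobin UMIs were found in 0.193% of TIL and 0 of 9128 IEL droplets (up to 0.0329%). When a cell had to hold a UMI of Trdc or a γ constant segment and none of Trac, the γδ T-like share was 22.0% in the IEL and 61.6% in the TIL library.

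The γδ T-like cells of the 2 libraries differed in their subsets. Cytotoxic-like cells, marked by genes such as Gzma, Ccl5 and Nkg7, made up 98.1% of IEL (97.8 to 98.4) and 9.55% of TIL γδ T-like cells (9.02 to 10.1). Recirculating-like cells, marked by Ccr7 and S1pr1, made up 5.97% of TIL (5.55 to 6.42) and 0.176% of IEL cells (0.101 to 0.286). Cycling-like cells made up 1.27% of TIL (1.08 to 1.49) and 1.08% of IEL cells (0.878 to 1.32).

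**Figure D1:**
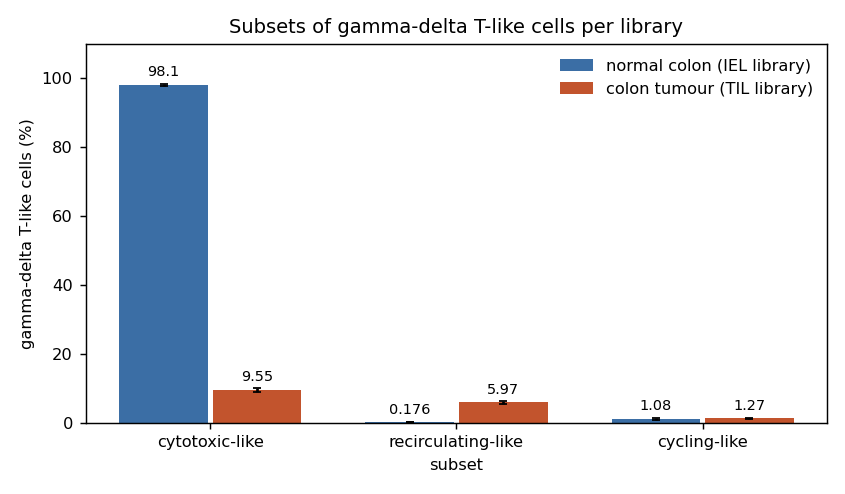
Share of γδ T-like cells in each subset shown (percent, vertical axis) for the normal-colon (IEL) and tumour (TIL) libraries; bars are shares and error bars exact 95% binomial intervals. Cytotoxic-like cells made up 98.1% of the IEL and 9.55% of the TIL γδ T-like cells.

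Most clusters drew nearly all of their cells from 1 library and may mark that library rather than a cell type. IEL cytotoxic-like cells lay mainly in clusters 3, 5, 6, 8 and 9, and TIL cytotoxic-like cells in clusters 11 (597 cells) and 12 (428 cells). Recirculating-like cells were cluster 10, with 700 TIL and 16 IEL cells. Cluster 9 was led by heat shock genes (Hspa1b, Hspa1a, Dnajb1) and cluster 21 by interferon-response genes (Rtp4, Ifit1, Isg15), so these mark a state among cytotoxic-like cells. The TIL cytotoxic-like share was 6.13% under a stricter filter on cells, where clusters of 3.32% of TIL cells went unnamed. Whether those cells account for the lower share was not tested.

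The second question, named in the design, was how γδ T cells of tumour and normal colon differed in expression. Tumour γδ T-like cells carried far more transcript of Il17a and of the growth factor gene Areg, and normal-colon cells more of heat shock genes, the chemokine gene Ccl4 and Tbx21, which encodes the type-1 transcription factor T-bet. Il17a, on chromosome 1 from 20730905 to 20734496, was at 4522 CPM in TIL and 9.12 CPM in IEL cells, a log2 ratio of 8.95 (8.84 to 9.07). Areg, on chromosome 5 from 91139599 to 91148432, was at 5717 against 10.4 CPM, 550-fold higher in TIL cells (511 to 593). Of 6328 genes measured at 20 CPM or more in either library, 697 were at least 2-fold higher in TIL and 876 at least 2-fold higher in IEL cells, and the median log2 ratio of all was -0.10.

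Of the 15 genes furthest above in TIL cells, several rested on very few UMIs in the IEL library: Gldc on 1, Lum, Mpzl1 and Csgalnact1 on 2, and Il1r2 and Rbm24 on 3. Gldc, encoding a glycine-cleaving enzyme, was at 92.3 CPM in TIL cells, a log2 ratio of 12.62 (10.14 to 17.93). Il17f was at 237 CPM against 0.132 CPM, a log2 ratio of 10.81 (9.89 to 11.94). Lum, Mpzl1, Il1r2, Rbm24, Tpbg, Csgalnact1, Mmp9, Ccr1 and Cxcl3 had log2 ratios between 9.02 and 10.80. Tff1 and S100a9 had no UMI in IEL cells and were at least 1036-fold and at least 518-fold higher in TIL cells, against a floor of 3 UMIs over the library. S100a9 is a transcript of myeloid cells, and the myeloid transcripts S100a8 and Lyz2 were at 16.2 and 6.07 CPM in the same TIL cells. Lum, a fibroblast marker, was at 52.2 CPM in TIL cells while the fibroblast transcripts Col1a2 and Col1a1 were at 1.99 and 0.221 CPM.

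The 15 genes furthest above in IEL cells were led by Scin, at 85.9 against 1.48 CPM, a log2 ratio of -5.86 (-6.13 to -5.61). Hspa1a, an inducible heat shock gene on chromosome 17 from 34969190 to 34972156, was at 770 CPM in IEL and 15.2 CPM in TIL cells (log2 -5.66). Ccl4 had a log2 ratio of -5.38 and Tbx21 of -4.20. Hspa1b, Zfp773, Hspb1, Fgr, Ppp2r2c, Actrt3, Cd200r2, Ddx43, Slc26a10, Cfap126 and Car2 lay between -5.20 and -4.20. Among the genes given whatever their ratio, Ifng was lower in TIL cells (log2 -3.60, -3.74 to -3.46), as were Tcf7 (-1.17, -1.24 to -1.10) and Tigit (-1.73, -1.91 to -1.56). Tigit, at 4.37 CPM in TIL and 14.5 CPM in IEL cells, lay below the 20 CPM floor in both and was not among the 6328 genes. Gzmb (-0.88), Lag3 (-0.98) and Tox (-0.33) were within 2-fold.

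**Figure D2:**
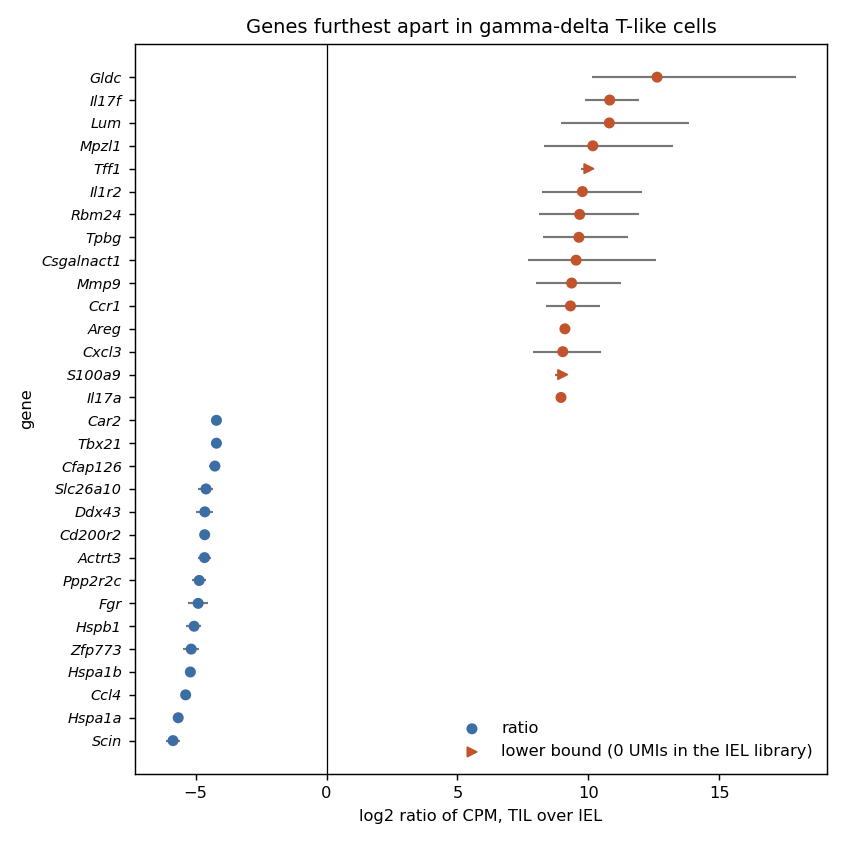
Log2 ratio of CPM (TIL over IEL, horizontal axis) in γδ T-like cells for the 15 genes furthest apart in each direction; points are ratios, triangles lower bounds for genes without UMIs in the IEL library, and lines 95% counting intervals. Gldc lies at 12.62 and Scin at -5.86.

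Gene groups fixed beforehand split between the libraries. Of 20 cytotoxic and type-1 genes, 13 were higher in IEL and 2 in TIL cells, with a median of -2.51; Ccl5 (-3.95) and Nkg7 (-2.96) were among the first, Gzmc (1.10) and Klrc1 (1.05) the others. Of 21 intraepithelial residence genes, 15 were higher in IEL cells, with a median of -2.30, including Gpr34 (-3.76), Itga1 (-3.66) and Cd8a (-3.26), while Itgb7 (1.31) and Il2rb (1.15) were higher in TIL cells. Chemokine receptor and homing genes had a median of 3.41, with 9 of 13 higher in TIL cells, such as Ccr2 (6.00), Cxcr4 (5.57) and Cxcr6 (3.63), and Ccr9 (-2.03) and Cxcr3 (-1.76) higher in IEL cells.

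Tumour cells also carried more transcript of repair and glycolysis genes, and of some activation genes. Of 16 glycolysis and hypoxia genes, 11 were higher in TIL and none in IEL cells, with a median of 1.62, led by Hif1a (4.08), the lactate transporter gene Slc16a3 (3.27) and Pgam1 (2.79). Of 6 tissue-repair and regulatory genes, 5 were higher in TIL cells, with a median of 2.46, including Hbegf (4.03) and Tgfb1 (1.70). Co-stimulation and activation genes had a median of 1.53, with 5 of 10 higher in TIL, such as Tnfsf11 (5.94), Il2ra (4.99) and Icos (4.76), and 3 of 10 higher in IEL cells, such as Cd27 (-2.44). Naive and memory-like genes had a median of 1.88, with Il7r (4.28), Ccr7 (3.64) and S1pr1 (3.41) higher in TIL and Id3 (-2.80) higher in IEL cells. Dissociation stress genes had a median of -1.08, with 9 of 17 higher in IEL cells, among them Fos (-3.68) and Dnajb1 (-2.49), and none in TIL cells.

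As a description of these libraries, each of these medians lay at percentile 99.98 or above, or at 0, among 10000 random lists matched on size and expression. Oxidative phosphorylation genes had a median of 0.48 (percentile 95.3), with Ndufa1 (1.70) and Ndufa4 (1.15) the 2 of 20 at least 2-fold higher in TIL cells. Exhaustion-associated regulators had a median of -0.09 (percentile 31.3), which was 0.00 with the median gene ratio set to 1. With the cell-wise rule the naive and memory-like median was 0.97. Among the regulators, Irf4 (2.42), Batf (1.67), Id2 (1.31), Prdm1 (1.30) and Bhlhe40 (1.12) were higher in TIL, and Nr4a2 (-2.23), Ikzf2 (-1.94) and Rgs1 (-1.33) in IEL cells.

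**Figure D3:**
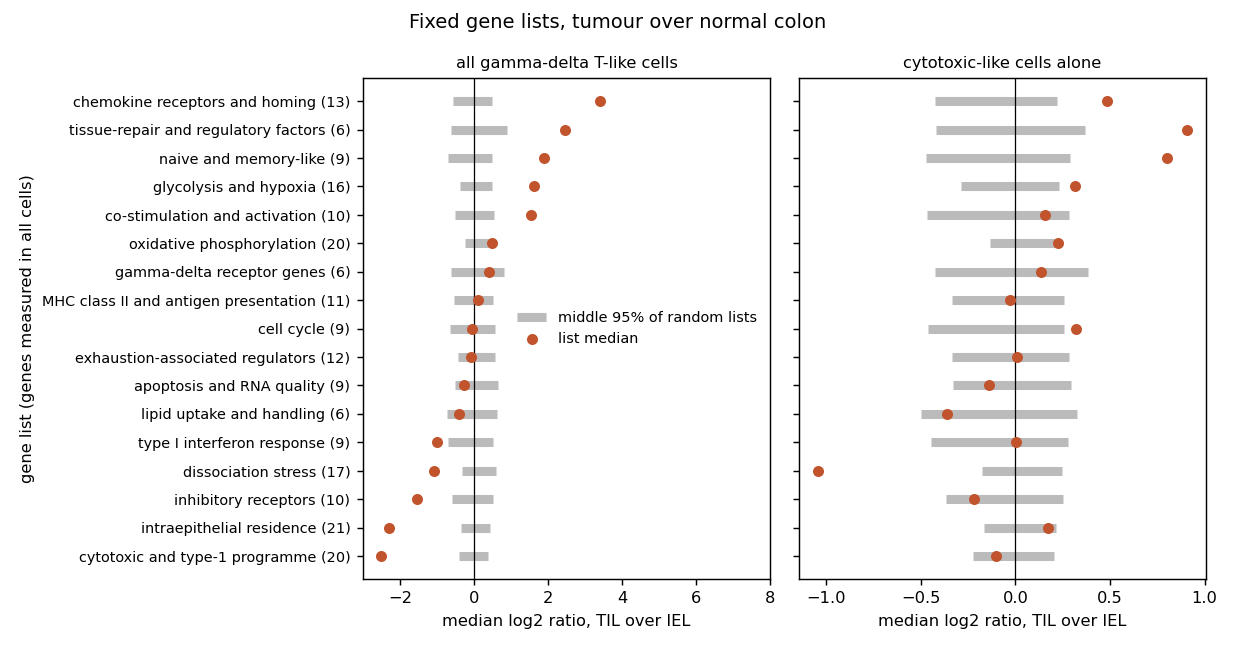
Median log2 ratio, TIL over IEL (horizontal axis), of fixed gene lists in all γδ T-like cells (left) and in cytotoxic-like cells alone (right); points are medians and grey bars the middle 95% of random lists. The cytotoxic and type-1 programme lies at -2.51 in all cells, and dissociation stress genes at -1.05 in cytotoxic-like cells alone.

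Within cytotoxic-like cells, tumour and normal colon were closer. Tumour cytotoxic-like cells carried more of the granzyme gene Gzmc, at 381 against 20.2 CPM (log2 4.24, 4.14 to 4.33), of the lymph node homing receptor gene Ccr7 (3.73, 3.49 to 3.97), of Cxcr4 (3.01) and of Il7r, the interleukin-7 receptor (2.10). Normal-colon cytotoxic-like cells carried more Hspb1 (log2 -4.77), Hspa1b (-3.16), Hspa1a (-3.11), Fos (-2.79) and Ccl4 (-2.68), and more Ifng (-1.35) and Tbx21 (-1.39). Of 6040 genes, 127 were at least 2-fold higher in TIL and 274 in IEL cytotoxic-like cells. Dissociation stress genes kept a median of -1.05 (percentile 0), and the cytotoxic and type-1 programme had -0.10 (percentile 14.8). Several genes of that programme, such as Gzma, Ccl5 and Nkg7, also named the subset, so its small median is partly set by the naming. Intraepithelial residence had 0.17 (93.1) and naive and memory-like genes 0.80 (99.99). Co-stimulation and activation genes had 0.16 (91.6) and glycolysis and hypoxia genes 0.31 (99.6). Tissue-repair genes, of which 5 were measured there, had 0.91 (100) and chemokine receptor and homing genes 0.48 (99.98).

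Of the genes apart between the libraries in all γδ T-like cells, 88 were also at least 2-fold higher in TIL and 204 in IEL cytotoxic-like cells. Chosen after their values were seen, examples are Cxcr4, Ccr7, Satb1 and Pgam1 for TIL, and Fos, Fosb, Jun, Hspa1a, Dnajb1 and Dusp1 for IEL cells. The TIL and IEL cytotoxic-like cells lay in different clusters. Cluster 12, with 428 of the 1119 TIL cytotoxic-like cells, had a mean log2 marker level of -0.71 for cytotoxic and 0.09 for recirculating markers. Whether the higher Ccr7, Il7r and Satb1 levels lie in cells with a clear cytotoxic programme was not tested. On the IEL side, cluster 5, with 2068 of the 8898 cytotoxic-like cells, had a mean log2 level of -0.20 for cytotoxic markers. Cluster 15, with 188 IEL cells, had -0.02, and the larger IEL clusters 3, 6, 8 and 9 had 0.70 to 0.94. The cytotoxic-like name therefore covers clusters of unequal marker level in both libraries. Free RNA with the make-up of the whole tumour library, scaled to give all Il17a UMIs of the TIL cytotoxic-like cells, would give 0.316% of their Gzmc, 2.90% of their Ccr7, 11.1% of their Il7r and 15.2% of their Cxcr4 level. It would give 29.5% of their Icos, 30.9% of their Il2ra and 95.6% of their Areg level, and without it these genes were 1.53-fold, 1.73-fold and 1.07-fold higher in TIL cells. Without it 104 of the 127 and 69 of the 88 genes were still at least 2-fold higher, and the medians of the tissue-repair, homing and glycolysis groups were 0.40, 0.40 and 0.22. The scale may be too high, since at this scale free RNA would give 142% of the Trdv4 level of TIL cytotoxic-like cells. The values without free RNA may therefore remove too much. The counts of genes ranged from 58 to 286 (higher in TIL) and from 118 to 698 (higher in IEL) over the alternatives tried.

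The series title names exhausted subsets, and the third question was which cells carried inhibitory receptor transcripts. Pdcd1, encoding PD-1, was at 553 CPM in TIL and 20.2 CPM in IEL γδ T-like cells, a log2 ratio of 4.77 (4.70 to 4.85). Ctla4 (2.45, 2.43 to 2.48) and Havcr2, encoding TIM-3 (2.21, 2.14 to 2.29), were also higher in TIL cells. Cd244a (-3.76), Entpd1 (-3.29), Cd200r1 (-2.88), Cd160 (-2.50) and Lilrb4a (-2.08) were higher in IEL cells, and the 10 measured inhibitory receptor genes had a median of -1.53 (percentile 0.020). Within cytotoxic-like cells that median was -0.22 (percentile 13.0). With the cell-wise rule the Pdcd1 log2 ratio was 3.45 and the median of the list -0.68. Cd244a, Entpd1 and Cd160 are also members of the intraepithelial residence list, and Cd160 is a fixed marker of the cytotoxic subset. The low median in all γδ T-like cells is therefore not independent of the residence and cytotoxic results.

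Within cytotoxic-like cells the receptors were closer between the libraries. Cytotoxic-like cells had a TIL over IEL Pdcd1 log2 ratio of 2.01 (1.85 to 2.17, and 0.90 to 3.13 over the alternatives), a Ctla4 ratio of -0.02 and a Havcr2 ratio of -1.10, and Havcr2 stood at 0.12 when genes were centred within each library.

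At 2000 UMIs per cell, 50.5% of TIL (49.5 to 51.4) and 7.11% of IEL γδ T-like cells (6.58 to 7.66) had UMIs of at least 2 of Pdcd1, Havcr2, Lag3, Tigit and Ctla4. Without thinning the shares were 78.8% and 33.4%, at median depths of 6389 and 6863 UMIs, and 55 TIL and 48 IEL cells were too shallow to thin. The share was 9.39% (7.73 to 11.3) in TIL cytotoxic-like, 4.90% (3.42 to 6.78) in TIL recirculating-like and 6.98% (6.46 to 7.53) in IEL cytotoxic-like cells. In TIL myeloid-like cells it was 12.4% (8.17 to 17.7) at a median of 7710 UMIs with 21 cells left out. The unthinned share there was 33.6%. Those cells were a poor measure of background, since Lag3 was found in 2.48% of them and 16.8% of TIL cytotoxic-like cells, and Havcr2 in 14.4% and 2.17%. With the free RNA part of each receptor removed, from 0.537% of the Tigit to 21.9% of the Havcr2 level, the TIL cytotoxic-like share was 8.21% (6.66 to 9.99), an interval that overlaps that of IEL cytotoxic-like cells, from which no free RNA was removed. The IEL library had too few myeloid-like cells for the same comparison.

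**Figure D4:**
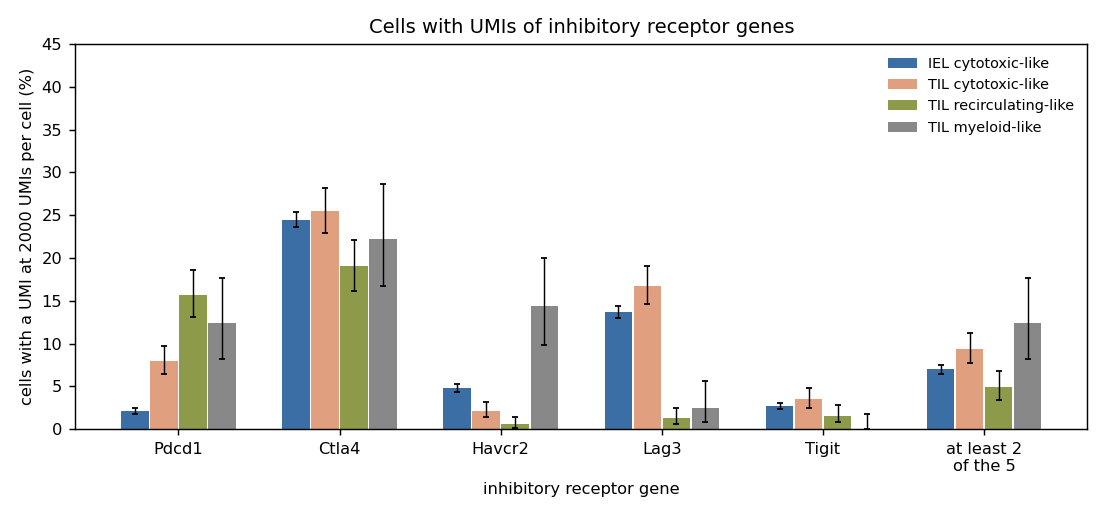
Share of cells with a UMI of each inhibitory receptor gene, and of at least 2 of the 5 (percent, vertical axis), at 2000 UMIs per cell; bars are shares per subset and error bars exact 95% binomial intervals. TIL cytotoxic-like cells reached 9.39% for at least 2 of the 5, against 12.4% in TIL myeloid-like cells.

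The fourth comparison was of γδ receptor genes. Trdv4, a δ variable segment, had a UMI in 32.8% of TIL (32.0 to 33.7) and 0.809% of IEL γδ T-like cells (0.635 to 1.02) at 2000 UMIs, and in 61.7% and 2.37% without thinning. Within the TIL library it was found in 4.46% of myeloid-like and 0.542% of cytotoxic-like cells, where free RNA would give 142% of its level. The constant segment Trdc, on chromosome 14 from 54142851 to 54148868, was at 3969 CPM in TIL and 815 CPM in IEL cells (log2 2.28, 2.27 to 2.30), with a UMI in 11083 of 11668 TIL and 6751 of 9021 IEL cells at 2000 UMIs, and in 37.6% of TIL myeloid-like cells. The 6 measured γδ receptor genes had a median of 0.41 (percentile 84.0), with Trdv4 (5.97), Trdc and Tcrg-C1 (1.31) higher in TIL cells. That median was -0.65 with genes from 5 CPM and 1.31 with genes from 50 CPM. Libraries of 3' ends read variable segments poorly and free RNA adds to them, so these shares do not measure usage.

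Trac, the α constant segment, had a UMI in 43.4% of IEL (42.4 to 44.4) and 15.2% of TIL γδ T-like cells (14.6 to 15.9) at 2000 UMIs, and in 77.9% and 37.4% without thinning. It was found in 3.47% (1.40 to 7.01) of TIL myeloid-like cells. The β constant genes Trbc1 (log2 -0.14) and Trbc2 (-0.18) were at nearly the same level in both libraries.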

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

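No test was run on the results in this part, and no explanation was weighed. They are droplets outside the γδ T-like class, picked out because they were at a higher share in the tumour library than in the normal-colon library. Myeloid-like droplets, with markers of macrophages or monocytes and of neutrophils, made up 1.80% of the tumour library and 0.0110% of the normal-colon library. Mixed, unnamed droplets made up 2.94% and 0.197%, or 2.45% and 1.83% with genes centred within each library. Epithelial-like droplets made up 0.403% and 0.110%, or 0.435% and 0.383% with genes centred within each library. Their direction turned under the looser filter on cells (0.167% and 0.925%), and the stricter filter left no cluster with that name. Haemoglobin-rich droplets, those at or above the limit on haemoglobin UMIs used to set droplets apart, made up 0.193% of the tumour library. In the normal-colon library 0 of 9128 droplets reached that limit, which allows a share of up to 0.0329%.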

How the results depend on the processing

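Clustering with the receptor genes and keeping haemoglobin-rich droplets were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because each group has 1 library. The lists named by the comparisons kept their direction and their side of the random-list range in 28 of 28 values, with medians of the cytotoxic programme from -2.69 to -2.36 and of inhibitory receptors from -1.62 to -0.68. Of 560 log2 ratios of named genes between the libraries, 0 reversed, 77 moved beyond their counting interval and 483 did not. Most of these genes were picked from the same data as the furthest apart, so a reversal was unlikely from the outset. A change of the expression floor alone leaves a gene's ratio the same by construction. The tally therefore says little about how stable smaller differences are. Pdcd1 ranged from 3.45 to 5.41 and Il17a from 6.95 to 9.06.

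With a class by cell (a UMI of Trdc or a γ constant segment and none of Trac), the γδ T-like share was 22.0% in IEL and 61.6% in TIL cells; its construction removes every cell with a Trac UMI. The cytotoxic-like share was then 96.5% in IEL and 6.61% in TIL cells, and the IEL share with at least 2 receptors 5.79% and with Trdv4 1.27%. With genes centred within each library, the γδ T-like share was 97.4% in IEL and 94.9% in TIL cells, and the cytotoxic-like share 98.8% and 11.0%. The log2 ratio of Havcr2 between TIL and IEL cytotoxic-like cells was then 0.12 in place of -1.10. With Leiden resolution 2.0, where clusters of 9.67% of IEL and 12.9% of TIL cells went unnamed, the γδ T-like share was 89.7% in IEL and 81.6% in TIL cells; among TIL γδ T-like cells 11.1% were cytotoxic-like, 46.9% had at least 2 receptors and 31.7% Trdv4. With the stricter filter on cells, the γδ T-like share was 99.7% in IEL and 92.0% in TIL cells. Clusters of 0.0558% of IEL and 3.32% of TIL cells then went unnamed. Among TIL γδ T-like cells 6.13% were cytotoxic-like, 52.3% had at least 2 receptors and 34.1% Trdv4. The looser filter gave γδ T-like shares of 98.8% and 93.4%, resolution 0.5 gave 99.66% in IEL, clustering with receptor genes 99.69% in IEL, and removing high-UMI cells a cytotoxic-like share of 98.5% in IEL cells. The cause of these differences was not tested.

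Counts of genes and shares of cells moved by construction with the fold, the floor and the depth. Genes higher in IEL and in TIL cells numbered 1649 and 1240 at 1.5-fold, 399 and 393 at 3-fold, 1688 and 1066 from 5 CPM, and 428 and 461 from 50 CPM. At least 1 receptor was found in 40.6% of IEL and 82.5% of TIL cells, and at least 3 in 0.466% and 11.999%. Without thinning, at least 2 receptors were found in 33.4% of IEL and 78.8% of TIL cells and Trdv4 in 2.37% and 61.7%, and at 1000 UMIs in 2.05% and 28.9%, and 0.353% and 20.3%. Depth limits the shares of cells with a receptor UMI, which move with the UMIs kept per cell.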

Other observations

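Tests chosen only after the result was seen were those of αβ T cells and of free RNA for Trac, and of free RNA or a difference within cytotoxic-like cells, with the allowance for free RNA in the test of the mix of subsets there.

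Type I interferon genes had a median log2 ratio of -1.01 (percentile 0.345), with Rtp4 (-2.59) and Ifi203 (-1.39) higher in IEL cells and Ifi27l2a (1.07) higher in TIL cells; within cytotoxic-like cells the median was 0.01 (percentile 67.6). Antigen presentation genes had a median of 0.10 (percentile 72.3) over members that went both ways, with H2-DMa (-1.96), H2-Aa (-1.84) and Psmb9 (-1.53) higher in IEL and Cd74 (148 against 64.7 CPM) higher in TIL cells. Cell cycle genes had a median of -0.05 (percentile 57.9), and of 0.32 (percentile 99.1) within cytotoxic-like cells. Lipid handling genes had a median of -0.41 (14.4), with Acadl (-1.70) higher in IEL and Plin2 (1.34) higher in TIL cells. Apoptosis and RNA quality genes had a median of -0.26 (12.1), with the survival gene Bcl2 (-2.62) higher in IEL cells. The sign of the cell cycle, antigen presentation and lipid medians turned under some alternatives. The Y-linked genes Ddx3y (128 CPM in TIL and 144 CPM in IEL cells) and Eif2s3y (93.6 and 111 CPM) were expressed in both libraries, and Xist had 5 and 4 UMIs. Foxp3 UMIs were found in 63 TIL cells, 31 of them in the mixed, unnamed cluster, and in 4 IEL cells.

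The first pattern weighed was the genes at least 2-fold apart between the libraries. For a different mix of subsets, 18.6% of the genes were apart in the same direction in cytotoxic-like cells alone (12.6% of those higher in TIL, 23.3% of those higher in IEL cells), between the bounds of 10% and 50% set beforehand. A different mix and differences within a subset therefore cannot be told apart as the main source. A difference between tumour and normal tissue stays open as untested, confounded with library preparation.

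The second pattern was the larger share of tumour cells with UMIs of at least 2 inhibitory receptors. Depth was argued against, since the share at 2000 UMIs was 7.10 times that of IEL cells. For free RNA or a difference within cytotoxic-like cells, these cells supplied 0.891 percentage points (0.729 to 1.08) of the tumour share of 50.5%. They made up only 9.55% of TIL γδ T-like cells, so they were too few to be the whole source whatever their receptors. That result does not bear on free RNA in the other TIL cells, which was not tested. For a different mix of subsets, the TIL share in cytotoxic-like cells was 1.34 times the IEL share and met the bound set beforehand, but that bound made no allowance for free RNA; with its part removed the TIL share was 8.21% (6.66 to 9.99), overlapping the IEL share of 6.98% (6.46 to 7.53). A different mix as the whole source and a mix with a small difference within cytotoxic-like cells therefore cannot be told apart. These intervals overlap, the make-up and scale of free RNA were assumed, and none was removed from the IEL library. Tumour against normal tissue stays open as untested.

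The third pattern was Trac UMIs in IEL γδ T-like cells. Of cells with a Trac UMI 74.6% had a Trdc UMI, against 75.0% of cells without, a difference of -0.490 percentage points, which argues against αβ T cells as the whole source. Doublets were argued against by median depths of 6945 and 6818 UMIs, a ratio of 1.02, and free RNA by shares from 24.6% in cluster 5 to 59.2% in cluster 6, a ratio of 2.41. Transcription of Trac by γδ T cells is a hypothesis that may account for it, and reads shared between neighbouring transcripts were not tested. No biological explanation was tested for the lower share in the tumour library.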
